A study of Ovis aries with 16 samples.

How the data were processed

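Small non-coding RNAs were sequenced from liver and muscle of 8 female sheep, 4 control ewes and 4 ewes exposed to testosterone before birth (prenatal T), which gives 16 libraries in 4 groups of 4. The labels' protocols name total RNA extracted with Trizol and a small RNA library kit from NEBNext. The ewe numbers in the labels show that liver and muscle libraries with the same number came from the same animal. Ewes 98, 131, 132 and 201 were controls and ewes 48, 185, 233 and 255 were exposed.

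Tables of 4 RNA classes were used: microRNAs (miRNAs), small nucleolar RNAs (snoRNAs), small nuclear RNAs (snRNAs) and long non-coding RNAs (lncRNAs). The submitters' processing notes name cutadapt 3.2, STAR 2.6.0c and featureCounts 1.6.1; the role and order of these tools, the read filters and the genome build are not given in the sources used here. The values deposited by the authors are a normalised signal, reads divided by a size factor for each library, and not raw counts. Within every library the values above 0 were whole multiples of what a single read is worth: 100% of 1432 miRNA, 4471 snoRNA, 1099 snRNA and 10585 lncRNA values came out whole within 0.001 reads. The median ratio of the values to the mean over libraries was the same in all 8 libraries of a tissue (0.995 in liver and 1.02 in muscle for miRNAs), but ran from 0.632 to 1.74 over all 16, so the authors' scaling was made within each class and each tissue. Values of liver and muscle are therefore not on a common scale as deposited.

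The recovered reads gave the depth. Over the 4 classes, liver libraries held 250251 to 887739 reads and muscle libraries 239871 to 1819374. Reads per liver library ran from 206304 to 755344 for miRNAs, 5278 to 13951 for snoRNAs, 270 to 1750 for snRNAs and 38399 to 124174 for lncRNAs. In muscle these ranges were 113522 to 885316, 2180 to 5766, 200 to 1740 and 122749 to 926854. Intervals for a share of reads in a single library are 95% Wilson intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate libraries of a group differed by far more than counting noise, with a chi-square per degree of freedom between 19.2 and 217 over all pairs, so none was treated as a duplicate.

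Control and prenatal T libraries were compared within each tissue and class with limma 3.58.1 in R 4.3.3 (linear models with a variance trend) on log2(value + 1), for features with a mean value of at least 5 over the 8 libraries. Fold changes are on this scale, which understates changes of low features. P-values were adjusted by the Benjamini-Hochberg method within a class, with a threshold of 0.05. The filter kept 81 of 105 miRNAs in liver and 64 in muscle, 161 and 110 of 694 snoRNAs, 21 and 28 of 1148 snRNAs, and 121 and 114 of 2973 lncRNAs. The same test with all 16 libraries in 4 groups gave the difference of the prenatal T effect between tissues. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. Liver and muscle of the 4 control ewes were compared on recovered reads scaled jointly by median-of-ratios factors over these 8 libraries; the deposited values had been chosen for this test, and the change was made once their scaling was known. The share of each class in the reads of a library was compared by a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286; the plan was to leave this test out unless a library had a single factor for all 4 classes. Each class had its own factor, so the condition was not met, and running the test on recovered reads departs from the plan. A test over the 35 regroupings of the ewes was applied to the correlation of effects between tissues.

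The comparison of control with prenatal T libraries was checked on simulated reads drawn from the means and spreads of the real libraries, with 20 simulations per class and tissue; the other tests were not simulated. Of miRNAs changed 2-fold, 69.5% were recovered in liver and 86% in muscle, and of those changed 4-fold 98.5% and 99%. For lncRNAs the shares were 10% and 18.5% at 2-fold and 51% and 83% at 4-fold. For snoRNAs they were 3% and 7.5%, then 41% and 51.5%, and for snRNAs 30% and 40%, then 81.7% and 93.8%. No recovered feature had the wrong sign, and at most 2% of unchanged features were called. Each simulation changed 20 features at once (6 snRNAs in liver, 8 in muscle), mixing 2-fold and 4-fold changes, and drew features independently. Many changes ease the adjusted threshold, so recovery of a few isolated changes may be lower, which was not simulated.

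Tests, filters, groups, 29 feature lists and the rule for named features were chosen before the data were examined, apart from the departures stated here. The lists hold miRNAs enriched in liver or muscle, the imprinted DLK1-DIO3 cluster, the let-7 family, miRNAs reported in insulin and glucose handling, in fibrosis or as androgen-responsive, erythroid, immune, and endothelial and mesenchymal miRNAs, and the miR-17/92 family, with 7 snoRNA, 7 snRNA and 4 lncRNA lists by symbol. The snoRNA and snRNA tables use numbered identifiers, so those lists (C/D box, H/ACA box, Cajal body, imprinted, RPL13A, GAS5 and pre-rRNA snoRNAs; U1, U2, U4, U5, U6, U7 and minor spliceosome snRNAs) matched 0 features. Of the lncRNA lists (imprinted and X-inactivation, snoRNA host, nuclear body and miRNA host lncRNAs) only GTL2, the sheep MEG3, matched, and it was below the filter in both tissues. After the tables were read, 6 lists defined by position were added: snoRNAs inside RPL13A, inside ribosomal protein genes, between GTL2 and DIO3 and inside LOC114110053, and lncRNAs with an annotated miRNA or snoRNA, or an annotated tRNA gene, inside. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Several miRNA lists matched only in part: the data held 2 liver-enriched, 1 muscle-enriched, 1 erythroid, 1 immune, and 3 endothelial and mesenchymal miRNAs. Members of a list are counted as higher or lower by the sign of the log2 fold change.

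Named features follow this rule. In each comparison of control with prenatal T, up to 10 higher and 10 lower features past the threshold are named by smallest p, or, where fewer than 5 pass, the 5 of smallest p. Between tissues the 5 highest in each tissue by fold change with a mean of at least 100 are named, for the difference of effects the 5 of smallest p per class, of each list up to 4 members of highest mean, and the 5 most abundant features of each class and tissue. Any other named feature was chosen after its values were seen.

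Names and neighbours of features were taken from the RefSeq annotation of ARS-UI_Ramb_v3.0, which held all 105 miRNA symbols, 621 of 694 snoRNAs, 1010 of 1148 snRNAs and 1372 of 2973 lncRNAs; it was used only for names and for which genes lie next to or inside each other, and no coordinates are given because the authors' build is not named. The class tables overlap. Of 153 tested lncRNAs, 75 are in the annotation, and 21 of these 75 hold a listed small RNA. The lncRNAs outside the annotation could not be checked. In 10 of the 21 the reads of the small RNA came within 10% of the reads of the lncRNA, so a value for such a lncRNA repeats that of the small RNA inside it. Copies may share reads: 6 of the 21 snRNAs tested in liver and 7 of the 28 in muscle had exactly the values of another copy, as had 15 of 161 and 14 of 110 snoRNAs, and single members are uncertain. Among miRNAs, 2 in each tissue had the values of another. In liver these were MIR29B-1 and MIR29B-2, which count as separate members of the insulin and glucose list and of the fibrosis list.

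The library numbers in the labels fall into 2 ranges, called library sets here: set 1 holds liver of ewes 98 and 48 and muscle of all ewes but 255, and set 2 holds the other 6 livers and muscle of ewe 255. The labels do not say what these numbers stand for. In liver each set holds both treatments (1 and 1, then 3 and 3); in muscle set 2 is a single prenatal T library; among controls, all 4 muscles and 1 liver are in set 1. Pairing by ewe was checked as the correlation of the deviations from the group means in liver and muscle: over the 8 ewes it ran from -0.174 to 0.441 for miRNAs, -0.278 to 0.744 for snoRNAs, -0.889 to 0.459 for snRNAs and -0.213 to 0.592 for lncRNAs. Fits with the ewe as a block were run for the tissue comparison and the difference of effects.

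Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 20, rescaling by median ratios, no variance trend, the library set as a covariate, all 16 libraries in a single fit, edgeR, DESeq2, the ewe block, and leaving out each library in turn. After the data were seen, scaling to the reads of the 4 classes together, set 2 alone in liver, and, for the tissue comparison, the deposited values and set 1 alone were added.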

Results

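Liver and muscle small RNA libraries of 4 control and 4 prenatal T ewes were compared to find non-coding RNAs that differ after exposure to excess testosterone before birth, a sheep model of metabolic and reproductive programming. Reads of miRNAs made up 81.5% ± 1.45 (SD, n = 4) of the reads in the 4 classes in control liver and 50.0% ± 1.34 in control muscle. Reads assigned to lncRNAs made up 15.7% ± 1.03 in control liver and 49.5% ± 1.40 in control muscle. Most of that muscle share was held by LOC105604459, which lies inside MIB1, with 56.7% ± 1.40 of lncRNA reads, and LOC105603743, with 32.7% ± 2.28. Reads of LOC105604459 were between 1.06 and 1.10 times those of MIR133 in each of the 8 muscle libraries and between 1.23 and 2.03 times in the 8 livers. Whether these features count the same reads was not tested. LOC105603743 and the leading liver lncRNA LOC114110111 are not listed in the annotation used. The muscle miRNA miR-1 and the liver miRNA miR-122, both in the lists chosen beforehand, are not among the 105 miRNAs in the data. Whether the reads of LOC105603743 and LOC114110111 come from a miRNA or another small RNA, rather than from a lncRNA, was also not tested. The lncRNA shares carry the same limit.

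Ranks of miRNAs and shares of miRNA reads here cover the 105 miRNAs in the data, so a miRNA absent from them cannot appear. Members of the liver-enriched and muscle-enriched lists are among those absent. Of the 105, the most abundant in control liver were MIR26A with 15.4% ± 1.91 of miRNA reads, MIR148A with 9.27% ± 1.26 and MIRLET7A with 8.33% ± 1.05. Next came MIR99A with 7.82% ± 0.448 and MIRLET7G with 5.98% ± 0.925. In control muscle MIR133, a regulator of muscle differentiation, took 52.5% ± 2.39 of miRNA reads, followed by MIR26A with 7.24% ± 0.312, MIRLET7A with 5.17% ± 0.373, MIRLET7G with 3.92% ± 0.447 and MIRLET7B with 3.50% ± 0.309. The leading snoRNA of both tissues was LOC114117067, with 9.64% ± 0.793 of snoRNA reads in control liver and 10.6% ± 1.58 in control muscle, followed by LOC114111353 inside the translation factor gene EIF4G1 with 4.21% ± 0.566 and 6.97% ± 0.680. In both tissues LOC114117661 came next (4.06% in liver), then LOC114117421 and LOC114115077 in liver with 3.99% and 3.34%, and LOC114117663 and LOC114111821 in muscle with 2.95% and 2.41%. LOC114110196 led the snRNAs with 7.87% ± 1.49 in control liver, followed by LOC114117117, LOC114117115, LOC114117112 and LOC114117113, and in control muscle LOC114117060 with 7.16%, LOC114117093 with 6.32%, LOC114110196 with 5.99%, LOC114117120 with 3.59% and LOC114117115 with 3.41% were highest. Liver lncRNA reads were led by LOC114110111 with 34.3% ± 5.54, LOC114118399 with 15.7% ± 2.46, LOC105608013 with 9.57% ± 1.99, LOC105602212 with 7.11% ± 0.251 and LOC105611269, which holds MIR181A-2, with 5.53%. After the leading pair, muscle lncRNA reads went to LOC114118399 with 2.35%, LOC114112617 with 2.25% and LOC105611269 with 1.19%.

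In liver, no miRNA, snoRNA, snRNA or lncRNA passed the test between prenatal T and control ewes. The typical miRNA differed little: the median absolute log2 fold change over 81 miRNAs was 0.15, against a median standard error of 0.25. The smallest p-values among miRNAs belonged to MIR381 with 9.18 ± 2.55 normalised reads in prenatal T and 5.69 ± 0.811 in control liver, and the muscle miRNA MIR133 with 149 ± 18.5 and 345 ± 318. Next came MIR154A with 7.22 ± 3.46 and 3.87 ± 1.66, MIR485 with 42.4 ± 10.2 and 57.3 ± 5.29, and MIR25 of the miR-17/92 family with 3736 ± 679 and 4667 ± 644 (n = 4 each, limma adjusted p = 0.959). MIR381, MIR154A and MIR485 lie in the DLK1-DIO3 cluster, where only the maternal chromosome expresses the miRNAs. Without liver of ewe 48 the log2 fold change of MIR25 went from -0.33 to -0.21. For MIR133 the spread among controls came from ewe 98, whose liver held 816 normalised reads. With limma, 0 features of any class had an unadjusted p under 0.05, and edgeR and DESeq2 also called 0.

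In the other classes of liver the features of smallest p did not pass. Among snoRNAs, LOC114110868 inside CCAR1 had 20.4 ± 3.03 normalised reads in prenatal T and 12.4 ± 5.53 in control liver, and LOC114114650 17.0 ± 3.75 and 10.3 ± 5.94. LOC114118580 inside the ribosomal protein gene RPL27A had 6.26 ± 4.61 and 12.6 ± 3.93, LOC114116762 inside TPT1 4.34 ± 1.80 and 7.44 ± 2.11, and LOC114115090 inside TNPO2 11.2 ± 4.36 and 17.2 ± 4.44 (n = 4 each, limma adjusted p = 0.982). Among snRNAs the smallest p belonged to LOC114115462, with 24.8 ± 9.10 and 34.3 ± 6.62 (limma adjusted p = 0.965), then LOC114111395 and LOC114117112, LOC114117113 and LOC114117114, whose values are nearly the same. Among lncRNAs, LOC105605322 had 9.54 ± 3.98 against 4.24 ± 1.28, LOC114117996 8.93 ± 2.49 against 4.34 ± 5.31 and LOC114116379 32.6 ± 7.68 against 21.8 ± 3.44. LOC114114883 had a log2 fold change of -1.45, and LOC101116622 had 5.70 ± 2.29 against 9.65 ± 2.33 (n = 4 each, limma adjusted p = 0.890). Leaving out 1 liver moved several of these log2 fold changes by over 1.5 times: from 0.80 to 0.45 for LOC114114650 and from 1.43 to 0.81 for LOC114117996 without ewe 131, from -1.33 to -0.53 for LOC114118580 and from -1.45 to -0.89 for LOC114114883 without ewe 233, from -0.62 to -0.35 for LOC114115090 without ewe 48, and from -0.40 to -0.093 for LOC114111395 without ewe 131. Restricted to library set 2, with 3 control and 3 prenatal T livers, limma called 0 features in every class.

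Of 7 miRNA lists tested in liver, the let-7 family, repressors of growth and insulin signalling genes, passed. All 7 of its members had lower means in prenatal T liver, with a median log2 fold change of -0.20, and camera gave an adjusted p = 0.0314, against an adjusted p = 0.587 with an estimated correlation. No member passed alone, with 0 adjusted over the list alone. MIRLET7A had 27544 ± 6015 normalised reads in prenatal T and 32181 ± 3958 in control liver, MIRLET7G 21751 ± 1731 and 23045 ± 3078, MIRLET7F 21221 ± 3502 and 23034 ± 5027, and MIRLET7I 10526 ± 1177 and 11125 ± 164. The call was lost without liver of ewe 98 (adjusted p = 0.0611), 131 (0.134), 201 (0.170), 48 (0.608), 233 (0.0561) or 255 (0.0698), and in library set 2 alone (0.366). With libraries scaled to the reads of the 4 classes together, 1 of the 7 members was higher. The DLK1-DIO3 list had 18 members higher and 12 lower (adjusted p = 0.476), the insulin and glucose list 5 and 2 (0.476) and the fibrosis list 6 and 3 (0.476). The androgen-responsive list had 2 and 2 (0.897), the endothelial and mesenchymal list 2 and 1 (0.476) and the miR-17/92 family 1 and 4 (0.308), and each list had 0 members adjusted over the list alone. Lists with fewer than 3 members were not tested. Their median log2 fold change was 0.024 for the liver-enriched MIR194 and MIR148A and -0.84 for MIR133 (-0.30 without liver of ewe 98). It was -0.24 for MIR16B, the only miRNA of the erythroid list in the data, and -0.10 for MIR150, which is abundant in lymphocytes. Of 5 added lists tested, none passed (smallest camera adjusted p = 0.783).

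In muscle, reads assigned to 4 lncRNAs fell in prenatal T ewes, and no lncRNA passed as higher. These are small RNA libraries, so whether the long transcripts differ, or which small RNAs the reads come from, was not tested. LOC114118460 fell from 51.3 ± 16.3 to 11.2 ± 2.45 normalised reads (SD, n = 4 each; log2 fold change -2.07, SE 0.30, limma adjusted p = 0.00378). LOC114112617, among the 5 most abundant muscle lncRNAs, fell from 9317 ± 5195 to 2033 ± 968 (-2.16, SE 0.43, adjusted p = 0.0269). LOC114113790, whose neighbours are the Notch target HES1 and the mitochondrial fusion gene OPA1, fell from 3595 ± 2175 to 776 ± 374 (-2.12, SE 0.47, adjusted p = 0.0354). LOC105607806, which lies between ALOXE3 and the clock gene PER1 and holds a glycine tRNA gene, fell from 32.7 ± 27.9 to 5.23 ± 0.383 (-2.12, SE 0.48, adjusted p = 0.0354). For each of them all 4 prenatal T libraries lay below every control. LOC105607806 held 355 reads over all 16 libraries and was near the floor in prenatal T muscle. In muscle of ewe 255, 3 lncRNA reads were worth 7.33 normalised reads, above the prenatal T mean of 5.23. Its SD of 0.383 is therefore an uncertain measure of the spread between ewes.

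**Figure D1:**
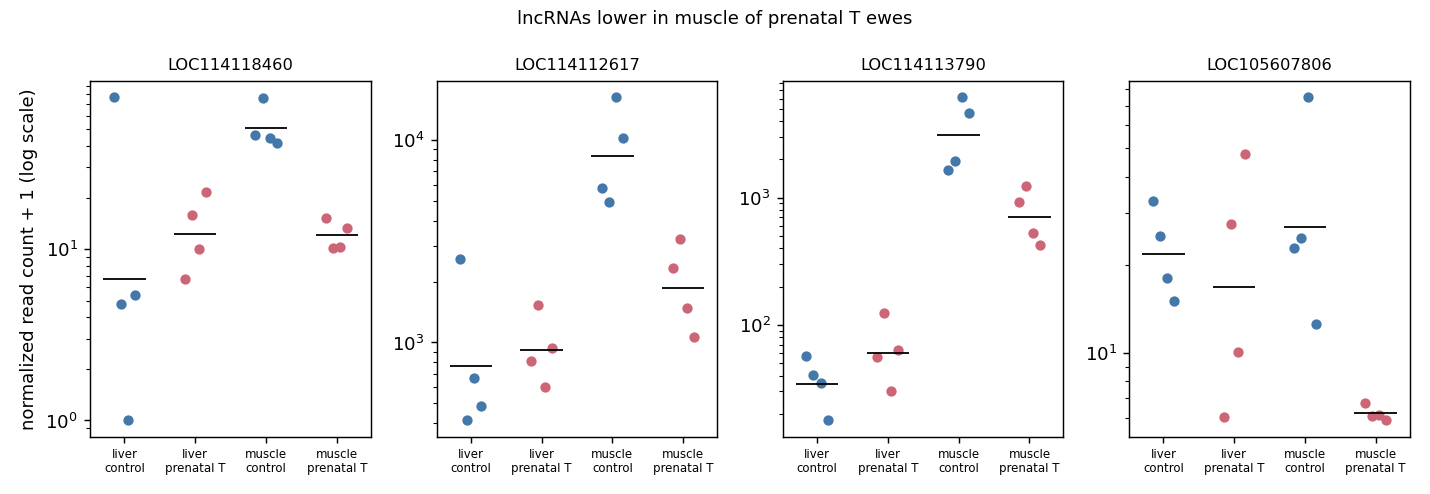
Normalised read count plus 1 (log scale) of the 4 lncRNAs that were lower in muscle of prenatal T ewes, per library in the 4 groups, with a bar at the mean of the log values. In muscle the 4 prenatal T libraries lie below the 4 controls in each panel, and in liver a single control, ewe 98, stands high for LOC114118460 and LOC114112617; the deposited values of the 2 tissues are scaled separately.

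The same 4 lncRNAs were called by edgeR and by DESeq2, which added LOC114112974 (151 ± 17.6 against 498 ± 385; DESeq2 adjusted p = 0.0365, limma adjusted p = 0.144). LOC114113790 and LOC114112617 moved together, with a correlation of their deviations within groups of 0.972 over the 8 muscle libraries, so they are not separate evidence; the ratio of their reads was 0.379 ± 0.0465 in muscle (n = 8) and 0.0581 ± 0.0242 in liver (n = 8). LOC105607806 missed the threshold with a pseudocount of 5 (log2 fold change -1.63, adjusted p = 0.0583), no variance trend (-2.12, 0.0558), rescaled libraries (-2.04, 0.0517) or libraries scaled to the reads of the 4 classes (-2.06, 0.0821). The calls fell to 1 without muscle of ewe 132, 48 or 233 and to 2 without that of ewe 131 or 201, with LOC114118460 still called in each. Within library set 1, without ewe 255, all 4 passed. With no variance trend 1 passed, LOC114118460, and with a single spread over both tissues 0 passed (adjusted p = 0.533 for LOC114118460 and 0.0508 for LOC114112617).

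No miRNA passed in muscle. The smallest p-values belonged to MIR10B, which lies in the HOXD cluster, with 1135 ± 178 normalised reads in prenatal T and 1512 ± 195 in control muscle, and the smooth muscle miRNA MIR143 with 6383 ± 2043 and 8824 ± 1859. They were followed by MIR433 of the DLK1-DIO3 cluster with 14.8 ± 9.62 and 6.20 ± 0.869, MIR374B with 25.5 ± 17.8 and 46.3 ± 9.93, and MIR21 with 483 ± 67.0 and 799 ± 438 (n = 4 each, limma adjusted p = 0.559). Single libraries carried much of this: without muscle of ewe 255 the log2 fold change went from -1.30 to -0.50 for MIR374B, from -0.51 to -0.26 for MIR143 and from 0.97 to 0.61 for MIR433, and without that of ewe 131 from -0.60 to -0.27 for MIR21. These 5 were the only miRNAs with an unadjusted p under 0.05, and edgeR and DESeq2 called 0.

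Among muscle snoRNAs the limma test called 0, with 0 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2. LOC114113389 inside the elongation factor gene EEF1B2 had 27.4 ± 3.83 normalised reads in prenatal T and 18.5 ± 4.09 in control muscle, and LOC114117067 519 ± 311 and 298 ± 42.5. LOC114117064 inside TRPV2 had 29.0 ± 33.6 and 8.21 ± 2.49, and LOC114109179 and LOC114109176, both between SNRPN and UBE3A and with nearly the same values, 16.8 ± 2.14 against 11.3 ± 3.29 and 11.5 ± 3.33 (n = 4 each, limma adjusted p = 0.873). Without muscle of ewe 255 the log2 fold change went from 0.65 to 0.29 for LOC114117067 and from 1.19 to 0.54 for LOC114117064, and without that of ewe 132 from 0.54 to 0.35 for LOC114109176.

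Among muscle snRNAs limma called 0, with 5 at an unadjusted p under 0.05, edgeR 4 and DESeq2 0. LOC114111412 had 17.2 ± 3.99 normalised reads in prenatal T and 30.1 ± 7.81 in control muscle (limma adjusted p = 0.105, edgeR 0.0128), and LOC114111395, between the same protein-coding genes, 16.9 ± 3.59 and 28.9 ± 8.04 (0.105 and 0.0128). LOC114115462 had 14.3 ± 3.27 and 21.6 ± 1.64 (limma adjusted p = 0.124, edgeR 0.0707). LOC114117093 and LOC114117060, both between TEX14 and RAD51C, had 22.1 ± 14.5 against 56.5 ± 20.7 (limma adjusted p = 0.142, edgeR 0.00814) and 25.6 ± 17.4 against 63.6 ± 21.3 (0.143 and 0.0147). With the library set as a covariate these last 2 snRNAs passed (limma adjusted p = 0.00484 and 0.00671) with smaller log2 fold changes, -0.95 and -0.92 against -1.64 and -1.66. Set 2 in muscle is ewe 255 alone, and the fit without that library gave the same fold changes and called 0 snRNAs. Reads may be shared between snRNA copies, so single members are uncertain.

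Of 7 miRNA lists tested in muscle, 2 passed. Of 54 DLK1-DIO3 cluster members among the miRNAs, 18 passed the filter in muscle. Of these 18, 16 had higher means in prenatal T muscle and 2 had lower means, with a median log2 fold change of 0.37 (camera adjusted p = 9.6e-07). Members below the filter are not in this tally. With an estimated correlation the list did not pass (adjusted p = 0.177), nor with fry (adjusted p = 0.473). No member passed, with 0 adjusted over the list alone. MIR127 had 1456 ± 245 normalised reads in prenatal T and 1212 ± 127 in control muscle, MIR379 91.0 ± 10.3 and 78.2 ± 11.7, MIR493 80.6 ± 21.0 and 68.3 ± 2.81, and MIR409 45.6 ± 19.9 and 35.1 ± 10.6, while MIR494 had 4.08 ± 3.35 and 8.40 ± 3.65.

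**Figure D2:**
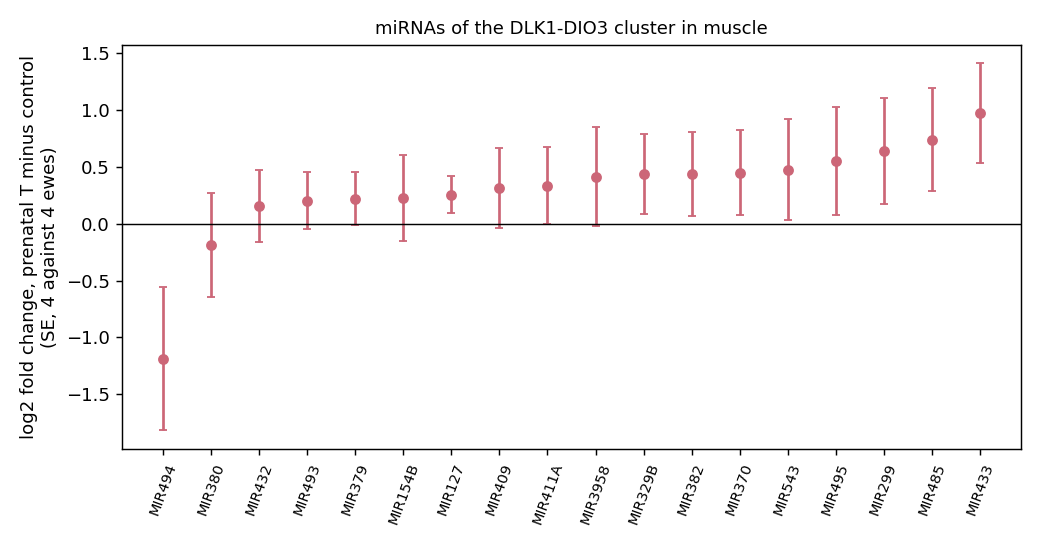
Log2 fold change between prenatal T and control muscle of the 18 miRNAs of the DLK1-DIO3 cluster that passed the filter in muscle, with standard errors from limma (4 against 4 ewes). Of the points, 16 lie above 0 and 2 below.

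Of the endothelial and mesenchymal list, miRNAs of vessel and stromal cells, the data held 3 members, MIR10B, MIR143 and MIR199A. All 3 were lower in prenatal T muscle, with a median log2 fold change of -0.42 (camera adjusted p = 0.0145). The other members of the list were not in the data, so the result covers only part of it. The adjusted p = 0.372 with an estimated correlation, 0 members passed, and 0 adjusted over the list alone. The list missed the threshold without muscle of ewe 132 (adjusted p = 0.0664), 48 (0.0690) or 255 (0.145). Of the insulin and glucose list 0 members were higher and 7 lower (adjusted p = 0.177), of the fibrosis list 0 and 6 (0.233) and of the androgen-responsive list 2 and 2 (0.520). Of the let-7 family 4 were higher and 3 lower (0.455) and of the miR-17/92 family 1 and 2 (0.822), and each of these lists had 0 adjusted over the list alone. Without muscle of ewe 255 the insulin and glucose list reversed (camera adjusted p = 0.998), and the fibrosis list had a camera adjusted p = 0.972. These 2 lists share members, so their tallies are not separate. The untested lists had median log2 fold changes of -0.23 (MIR148A and MIR194), -0.17 (MIR133), -0.028 (MIR16B) and -0.19 (MIR150). Of 5 added lists none passed (smallest camera adjusted p = 0.770); LOC105607806 was the called member of the lncRNAs with a tRNA gene inside.

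Whether prenatal T acted differently in liver and muscle was tested as the difference of the effects over all 16 libraries. No feature passed. The largest signals came from the lncRNAs that fell in muscle: LOC114113790 had a log2 fold change of 0.80 in liver and -2.12 in muscle (difference 2.92, SE 0.73, limma adjusted p = 0.116), LOC114112617 0.26 and -2.16 (difference 2.42, SE 0.75, adjusted p = 0.310) and LOC114118460 0.88 and -2.07 (difference 2.95, SE 1.21, adjusted p = 0.899). Then came LOC114118294 with -0.89 and 0.38 and LOC114116379 with 0.54 and -0.43. Among miRNAs the smallest p-values were those of MIR485, with -0.45 in liver and 0.74 in muscle, MIR374B with 0.16 and -1.30, MIR369 with 0.22 and 1.41, MIR494 with 0.075 and -1.19 and MIR370 with -0.32 and 0.45 (adjusted p = 0.752). Among snoRNAs they belonged to LOC114111812, LOC114117067, LOC114110522, LOC114111265 and LOC114113389 (adjusted p = 0.917), and among snRNAs to LOC114117093 and LOC114117060 (adjusted p = 0.443), LOC114108902, LOC114109164 and LOC114117112 (0.498). Single libraries carried several of these differences. Without muscle of ewe 255 they went from 1.26 to 0.61 for MIR494, from 1.45 to 0.66 for MIR374B, from -0.90 to -0.54 for LOC114117067 and from 1.69 to 1.0 for LOC114117093. The same library took LOC114117060 from 1.70 to 0.95 and LOC114109164 from 2.12 to 1.38. Without liver of ewe 255 LOC114117112 went from -0.65 to -0.32. With limma 2 miRNAs, 0 snoRNAs, 2 snRNAs and 5 lncRNAs had an unadjusted p under 0.05; edgeR called 1 lncRNA, LOC114113790, and DESeq2 0. Without liver of ewe 98 the 3 lncRNAs LOC114113790, LOC114112617 and LOC114118460 passed (adjusted p = 0.0234, 0.00682 and 0.00359), so the effect in muscle and the absence of a call in liver are not shown to differ in the full set.

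Across features, the prenatal T effects of liver and muscle were no more related than under other groupings of the ewes. Pearson's r of the log2 fold changes was -0.113 over 64 miRNAs, -0.114 over 105 snoRNAs, -0.337 over 21 snRNAs and -0.231 over 82 lncRNAs, with Spearman's rho of -0.171, -0.224, -0.181 and -0.190. Of 35 regroupings of the 8 ewes, 26, 28, 21 and 18 gave an r as large in size. Features are not independent replicates, and these were 4 relations of a single family.

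The tissues themselves differed in most miRNAs of the control ewes. Of 76 miRNAs, 32 were higher in liver and 26 in muscle relative to the joint scale. MIR133 had 338054 ± 26015 normalised reads in muscle and 199 ± 172 in liver (n = 4 each; log2 difference, liver minus muscle, -11.06, SE 0.41, limma adjusted p = 5.41e-10), and MIR10B 2341 ± 344 and 62.5 ± 29.4 (-5.30). Liver was marked by the epithelial miRNAs MIR200B, with 1158 ± 555 in liver and 5.21 ± 2.52 in muscle (7.51, SE 0.35), and MIR200A (6.39). Liver also held more of MIR194, with 5468 ± 1100 and 100.2 ± 29.6 (5.79), of MIR148A with 21288 ± 3949 and 1772 ± 365 (3.59), and of MIR152 (2.64). MIR150 was higher in muscle (-2.83), as were MIR181A-2 (-1.76) and MIRLET7B (-1.74), both of which turn to higher in liver with libraries scaled to the reads of the 4 classes (0.44 and 0.46).

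By list, both liver-enriched miRNAs measured, MIR194 and MIR148A, were higher in liver, and MIR133 was higher in muscle. Of 26 DLK1-DIO3 miRNAs 18 were higher in liver, 0 in muscle and 8 did not pass, with a median log2 difference of 1.47; MIR379 had 399 ± 45.1 in liver and 121 ± 16.6 in muscle. Of the let-7 family 6 of 7 were higher in muscle on the joint scale, but 5 were higher in liver in the deposited values and all 7 with scaling to the reads of the 4 classes. Of the insulin and glucose list 1 was higher in liver and 3 in muscle, of the fibrosis list 5 and 2, of the androgen-responsive list 2 and 1, of the endothelial and mesenchymal list 1 and 1, and of the miR-17/92 family 2 and 1, while MIR16B and MIR150 were higher in muscle. With scaling to the reads of the 4 classes all members of the insulin and glucose, fibrosis, androgen-responsive and miR-17/92 lists and MIR16B were higher in liver.

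Of 126 lncRNAs, 39 were higher in liver and 38 in muscle. LOC114110111 had 22030 ± 8633 in liver and a mean of 182 in muscle (log2 difference 6.87, SE 0.35, limma adjusted p = 3.63e-08), followed by LOC106990385 (4.87), LOC101116687 (3.86), LOC105616344 (3.63) and LOC114116957 (1.56), which repeats the snoRNA LOC114117067 inside it. LOC105603743 had 150311 ± 33135 in muscle and 106 ± 106 in liver (-11.36, SE 0.80), and LOC105604459 258071 ± 34185 and 371 ± 141 (-9.50). LOC114113790 (-6.71), LOC114112617 (-3.67) and LOC105606221 (-2.22) were also higher in muscle.

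Of 160 snoRNAs, 33 were higher in liver and 19 in muscle. Muscle held more of LOC114111821 inside DKC1, the gene of the pseudouridine synthase dyskerin, which had 4.54 ± 1.95 in liver (log2 difference -4.40, limma adjusted p = 3.17e-05). The snoRNAs highest in liver were LOC114110194 (3.70), LOC114113382 inside the nucleolin gene NCL (3.06), LOC114115928 inside RPL4 (2.98), LOC114117421 (1.99) and LOC114115077 inside RACK1 (1.34). LOC114113382 lost its call without any 1 of 7 of the 8 libraries (adjusted p between 0.0723 and 0.103), all but liver of ewe 98. Tissue and library set overlap among controls. A fit within set 1 had to take both treatments, with a treatment term, over 2 liver and 7 muscle libraries, so it differs from the control comparison in set, treatments and number of livers. In it 22 snoRNAs passed, LOC114117421 kept its call (1.38), and LOC114110194 (0.14), LOC114113382 (-0.10), LOC114115928 (-0.29) and LOC114115077 (0.50) did not pass. The same fit called 52 miRNAs, 9 snRNAs and 74 lncRNAs.

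Of 25 snRNAs, 9 were higher in liver and 0 in muscle, 7 of them with nearly the same values, such as LOC114117112 with 62.8 ± 14.1 in liver and 24.6 ± 3.46 in muscle (log2 difference 1.30, limma adjusted p = 0.00019). These counts depend on the scale. The joint scale left the median log2 difference at 0.13 for miRNAs, 0.20 for snoRNAs, -0.77 for snRNAs and -0.019 for lncRNAs. In the deposited values it was 1.52, 1.27, -1.21 and 0.24, and with scaling to the reads of the 4 classes 2.33, 2.31, -0.055 and 1.26. The calls higher in liver and in muscle were 56 and 4 for miRNAs, 80 and 5 for snoRNAs and 8 and 14 for snRNAs in the deposited values, and 71 and 4 for miRNAs, 139 and 2 for snoRNAs, 0 and 0 for snRNAs and 66 and 11 for lncRNAs with scaling to the reads of the 4 classes. Rescaling by median ratios over the tested features gave 8 and 8 snRNAs.

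No share of reads in a class passed the test between prenatal T and control ewes. In liver, snoRNAs took 1.89% ± 0.712 of reads in prenatal T and 2.59% ± 0.312 in control ewes (n = 4 each, two-sided exact permutation p = 0.0857, adjusted 0.305 over 8 comparisons), miRNAs 82.9% ± 1.51 and 81.5% ± 1.45 (exact p = 0.257), snRNAs 0.144% ± 0.0498 and 0.222% ± 0.197 (exact p = 0.743). The share of lncRNAs was 15.7% ± 1.03 in control liver and differed by -0.661 percentage points (exact p = 0.343). In muscle, miRNAs took 48.2% ± 0.710 and 50.0% ± 1.34 (exact p = 0.0857, adjusted 0.305), lncRNAs 51.1% ± 0.418 and 49.5% ± 1.40 (exact p = 0.114), snRNAs 0.0786% ± 0.0141 and 0.128% ± 0.0646 (exact p = 0.286) and snoRNAs 0.558% ± 0.574 and 0.342% ± 0.0537 (exact p = 0.971). The smallest p this design allows is 0.0286, so a single share could not pass alone after adjustment over the 8 comparisons, whatever its size. That none passed therefore says little. In muscle, miRNAs and lncRNAs hold nearly all reads, so their differences are not separate tests. Without liver of ewe 48 the liver difference went from -0.702 to -0.349 percentage points for snoRNAs and from 1.44 to 0.727 for miRNAs, and without that of ewe 98 from -0.661 to -0.304 for lncRNAs. Without muscle of ewe 98 the muscle snRNA difference went from -0.0494 to -0.0276. Without muscle of ewe 201 the muscle differences of miRNAs (-2.34) and lncRNAs (2.23) reached an exact p of 0.0286 each, unadjusted. Muscle of ewe 255 held 1.42% snoRNA reads (95% Wilson interval 1.37% to 1.47%) and without it the muscle difference turned to -0.0708 percentage points; without liver of ewe 98, which held 0.517% snRNA reads (interval 0.494% to 0.542%), the snRNA difference in liver turned from -0.0779 to 0.0204. Within library set 1 in muscle, the 3 prenatal T libraries held 0.234% to 0.317% snoRNA reads and the 4 controls 0.267% to 0.386%.

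**Figure D3:**
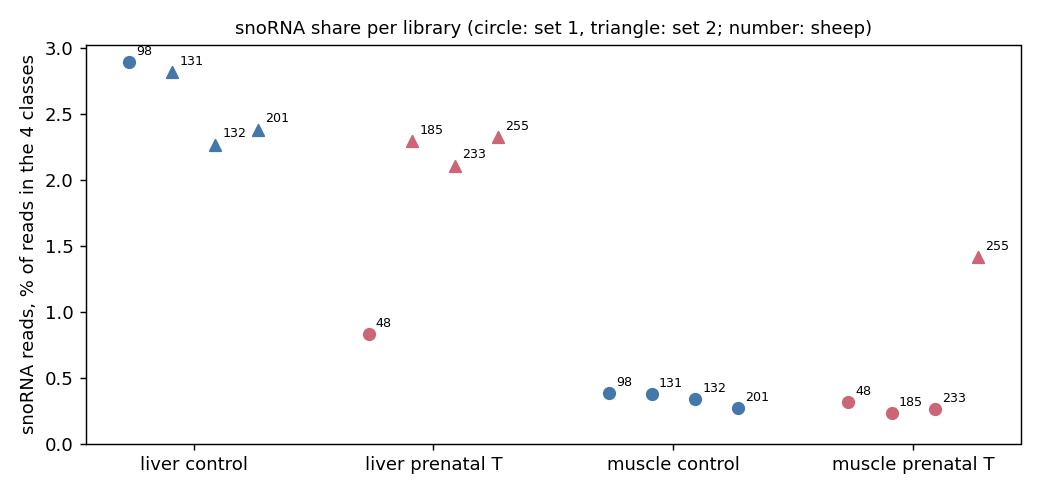
Share of snoRNA reads among the reads of the 4 classes (percent) in each of the 16 libraries, by group, with circles for library set 1, triangles for set 2 and the ewe number beside each point. Muscle of ewe 255, at 1.42%, is the only muscle library of set 2, and liver of ewe 48, at 0.830%, is 1 of the 2 livers of set 1.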

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

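The tests of the 3 patterns weighed here and the regroupings of control and prenatal T libraries were chosen after the results were seen, while the regroupings for the tissue comparison and for the difference of effects were chosen before.

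Of 100 groups of 4 libraries examined, 7 held a library far from the other 3, where chance gives about 1 in 20. Liver of ewe 98 held 0.517% snRNA reads, against 0.113% to 0.131% in the other controls. Liver of ewe 48 held 0.830% snoRNA reads, against 2.11% to 2.32% in the other prenatal T livers. Muscle of ewe 255 held 1.42% snoRNA reads, against 0.234% to 0.317% in the other prenatal T muscles. MIR485 had 49.4 normalised reads in liver of ewe 131, against 59.6 to 60.3 in the other controls. The snoRNA LOC114110868 had 24.9 in liver of ewe 48, against 18.6 to 19.1 in the other prenatal T livers. The lncRNA LOC105605322 had 3.63 in liver of ewe 233, against 10.7 or more in the other prenatal T livers, and the snRNA LOC114111395 had 41.0 in muscle of ewe 132, against 24.5 to 25.7 in the other controls.

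The first pattern is the snoRNA profile of muscle of ewe 255, the only muscle library of set 2. This library was also the shallowest in muscle, with 239871 reads over the 4 classes. Whether its depth accounts for the profile was not tested. RNA from liver in that library is argued against: 4 liver-high RNAs stood at a median of 0.400% of their liver level. The library set stays open, since the set 2 minus set 1 difference across 105 snoRNAs in muscle correlated with that in liver at a Pearson r of 0.840 (rho 0.715). Against control livers, which share no ewe with the muscle side, r was 0.724; against prenatal T livers it was 0.867, where ewes 255 and 48 stand on the same sides in both tissues, so an ewe effect is mixed with the set there. The library set may therefore account for this profile, but no range expected without a set effect was computed for these r. Over 35 regroupings of the ewes, the correlation of snoRNA effects between tissues, a different contrast, ran from -0.686 to 0.746. The r of 0.724 lies within that range. The snoRNA share itself does not follow the sets in liver, where set 1 held 0.830% (ewe 48) and 2.89% (ewe 98) and set 2 between 2.11% and 2.82%. SnoRNAs are not independent replicates, the muscle side rests on 1 library, and no biological explanation was tested.

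The second pattern is the fall of reads assigned to 4 lncRNAs in prenatal T muscle. The library set is argued against, since 4 passed without muscle of ewe 255. Depth is argued against too, since 2 of the 4 prenatal T muscle libraries, all of which held the lower values, had a depth inside that of the controls (817350 to 936046 reads). Scaling within the class is argued against, since 3 passed with libraries scaled to the reads of the 4 classes, and LOC105607806, which did not (adjusted p = 0.0821), kept a log2 fold change of -2.06 against -2.12. Prenatal T may be the cause, as a hypothesis from the same data, and other differences between these ewes stay open as untested.

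The third pattern is the level of muscle RNAs in liver of ewe 98. Among the 3 features with over 10% of muscle reads, the excess over the other livers was 0.614% of the muscle level for LOC105604459, 0.582% for MIR133 and 0.414% for LOC105603743, a ratio of highest to lowest of 1.48, which is what a small amount of muscle RNA in that library could give; the first 2 of these RNAs may count some of the same reads, which was not tested. Index misassignment within set 1 stays open: the median excess of these 3 features in liver of ewe 48 was -0.00936%, but that is a single other library. Muscle RNA is argued against as the source of LOC114112617, whose excess share was 172 times that of MIR133, and the excess was 644% of the muscle level for LOC114118460, 339% for LOC114112974 and 15.4% for LOC105603956, which a single share of muscle RNA does not give. What raised these lncRNAs in that liver was not tested.

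Regrouping the libraries or ewes into 4 and 4 gave 35 splits. For lncRNAs in muscle the real grouping called 4 and no other split more than 0, so it was 1 of 35, the smallest share this design can give. This argues against chance for that test alone and does not exclude it over the 8 treatment tests, and 0 passed with all 16 libraries in a single fit. Between tissues the real grouping was 1 of 35 in each class, with 58 miRNAs against a highest other of 0, 52 snoRNAs against 14, 9 snRNAs against 8 and 77 lncRNAs against 0. For the remaining treatment tests and for the difference of effects the real count was 0, which all 35 splits reach by construction, so the splits say nothing about chance there. Their highest other splits called 1 miRNA in liver, 0 in muscle and 1 for the difference, 0 snoRNAs in each, 1 lncRNA in liver and 0 for the difference, and 0 snRNAs in muscle. A split of the livers (98, 131, 185 and 255 against the rest) called 21 snRNAs and a split of the ewes (98, 132, 201 and 48 against the rest) 18 for the difference. These are the highest splits, picked after the fact. Apart from the real grouping, 1 split of the livers and 3 of the ewes called any snRNA. Copies share values, so these are not separate calls, and their source was not tested.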

How the results depend on the processing

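The alternatives added after the data were seen are scaling to the reads of the 4 classes, set 2 alone in liver, and the deposited values and set 1 alone for the tissue comparison; all others were chosen before, though the test of class shares was run against the plan. Apart from leaving out libraries, named features and lists kept their direction and their side of the threshold in 951 cases, lost the call in 21, gained it in 13 and reversed in 7, and counts, shares and correlations stayed close in 184 and moved in 23. A feature or list with no call in either fit and the same sign counts as kept, and a count of 0 that stays 0 as close. These totals therefore say little about how firm the treatment calls are. The cause of a change was not tested unless stated. The ewe block changed no count of calls by over 1.5 times. Scaling to the reads of the 4 classes moved the median treatment log2 fold change from -0.043 to -0.56 for snoRNAs and from -0.23 to -0.40 for snRNAs in liver, from -0.25 to -0.56 for snRNAs in muscle and from -0.081 to -0.29 for lncRNAs in liver.

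Between tissues, snoRNA calls were 85 in the deposited values, 141 with scaling to the reads of the 4 classes and 22 in set 1 alone, against 52. The set 1 fit takes both treatments, so its change cannot be put down to the set alone. The snRNA calls were 16 with median ratio rescaling, 18 with edgeR, 22 in the deposited values and 0 with scaling to the reads of the 4 classes, against 9. The lncRNA calls were 133 with no filter and 36 with a mean of at least 20, where more and fewer were tested, against 77. MIR181A-2 reversed to 0.44 and MIRLET7B to 0.46 with scaling to the reads of the 4 classes, and LOC114113382 to -0.10 and LOC114115928 to -0.29 in set 1 alone. For prenatal T in muscle, snRNA calls were 4 with no filter, 2 with the library set as a covariate and 4 with edgeR, against 0, and lncRNA calls 1 with no variance trend and 0 with all 16 libraries, against 4. LncRNAs with a difference of effects numbered 2 with no filter and 1 with edgeR. With an estimated correlation or fry 0 lists passed in liver and 0 in muscle, and 0 in liver in set 2 alone, where the fibrosis and androgen-responsive lists (adjusted p = 0.287) and the endothelial and mesenchymal list (0.918) reversed. With a mean of at least 20 the correlation of effects was -0.349 for miRNAs and -0.992 for snRNAs. The snRNA value rests on fewer than the 21 snRNAs of the main setting, some of them copies with the same values. It therefore does not show opposed effects in the 2 tissues.

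Leaving out each library in turn, snoRNA calls between tissues ran from 30 to 77 (30 without liver 131, 33 without liver 132, 31 without liver 201 or muscle 201), snRNA calls from 8 to 19 (19 without liver 98, 18 without liver 131, 14 without muscle 131), and LOC114113382 from 2.64 to 4.29, with its call lost without any library but liver 98 (adjusted p = 0.0723 to 0.103). The lncRNA calls in muscle ran from 1 to 4 and those for the difference of effects from 0 to 3 (3 without liver 98). Log2 fold changes in muscle ran from -2.43 to -1.84 for LOC114112617, from -2.43 to -1.79 for LOC114113790 and from -2.48 to -1.63 for LOC105607806. In liver, LOC114117112 and LOC114117113 ran from -0.49 to 0.044 and LOC114117114 from -0.49 to 0.047, reversed without liver 255. Passing lists ran from 0 to 2 in liver (2 without liver 185) and from 1 to 2 in muscle (1 without muscle 132, 48 or 255).

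Adjusted p of lists in liver ran from 0.00202 (without 185) to 0.861 for DLK1-DIO3, reversed without 201 (0.861), 233 (0.470) or 255 (0.530); from 0.00498 to 0.608 for let-7; from 0.168 to 0.783 for fibrosis, reversed without 98 (0.771) or 48 (0.779); from 0.456 to 0.973 for the androgen-responsive list, reversed without 98 (0.550), 48 (0.779) or 185 (0.675); and from 0.138 to 0.973 for the endothelial and mesenchymal list, reversed without 48 (0.779). In muscle they ran from 0.105 to 0.972 for let-7 and from 0.0501 to 0.998 for insulin and glucose, both reversed without 255, from 0.00362 to 0.145 for the endothelial and mesenchymal list, and from 0.506 to 0.998 for miR-17/92, reversed without 98 (0.990), 132 (0.992) or 185 (0.801). For DLK1-DIO3 in muscle the camera adjusted p at the preset correlation ran from 2.31e-08 without 48 to 0.000911 without 255.

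The correlation of effects ran from -0.282 to 0.124 for miRNAs and from -0.474 to 0.490 for snoRNAs, both highest without liver 48, and from -0.670 to 0.531 for snRNAs (0.180 without liver 132, 0.173 without 201, 0.531 without 255). For lncRNAs it ran from -0.557 without liver 98 to -0.0260 without liver 48, against -0.231. Differences in share ran from -0.115 to 0.0204 percentage points for liver snRNAs, reversed without 98, from -0.0708 to 0.324 for muscle snoRNAs, reversed without 255, from -2.34 to -1.41 for muscle miRNAs and from 1.25 to 2.23 for muscle lncRNAs, the last 2 past the threshold without muscle 201 (exact p = 0.0286, unadjusted). In simulated reads 3% of snoRNAs changed 2-fold were recovered in liver and 7.5% in muscle, so changes of that size are not excluded by a count of 0. Of snRNAs, the class of fewest reads, 30% and 40% were recovered, but the classes also differ in the number of tested features. What depth alone limits was not tested.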

Other observations

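The lists by position, all chosen after the tables were read, describe small RNAs by the gene that holds them. Between control liver and muscle on the joint scale, 6 of 27 snoRNAs inside ribosomal protein genes were higher in liver and 2 in muscle, with a median log2 difference of 0.50, and of 3 inside RPL13A 1 was higher in liver. Inside the lncRNA LOC114110053, 4 of 5 snoRNAs were higher in liver and 0 in muscle (median 1.73). A member, LOC114110194, went from 3.70 to 0.14 (adjusted p = 0.819) in the fit within library set 1, which takes both treatments; tissue and set overlap among controls. The single snoRNA tested between GTL2 and DIO3 did not pass (1.01). Of 19 lncRNAs with an annotated miRNA or snoRNA inside, 10 were higher in liver and 3 in muscle (median 1.08), and of 8 with a tRNA gene inside 3 and 1 (median -0.21).

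Between prenatal T and control ewes the snoRNAs inside LOC114110053 had 2 log2 fold changes above 0 and 4 below in liver (median -0.44) and 4 above and 0 below in muscle (median 0.56). Muscle of ewe 255, the only muscle library of set 2, stood apart: LOC114110194 had 121 normalised reads there against 3.66 to 8.11 in the other 3 prenatal T muscles. The snoRNAs inside ribosomal protein genes had 16 and 13 in liver and 11 and 9 in muscle. None of these lists passed (smallest camera adjusted p = 0.783 in liver and 0.770 in muscle).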
